A study of Homo sapiens with 6 samples.

How the data were processed

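Total RNA was extracted with TRIzol from 3 melanoma lines (501Mel, WM3912 and WM8), each transfected with an siRNA against ASAH1 or with a control siRNA, and per the labels every sample had an RNA integrity number of 10. The RNA was amplified and labelled with Cy3 by the Agilent low-input QuickAmp method and hybridised to 6 arrays, which per the file headers sat on 1 slide and were read in 1 scan, so no block for slide or scan could be fitted. The labels state neither the sequence nor the number of siRNAs, so that effects other than those through ASAH1 cannot be separated, nor do they state whether cultures were separate. No level of a group was measured on more than 1 array within a line. The same cell line pairs a control with a knockdown array. As a check of the pairs, deviations from the group mean were correlated across genes between control and knockdown arrays, with r of 0.097, 0.319 and 0.213 within 501Mel, WM3912 and WM8 and of -0.30 to 0.092 between lines.

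Per the file headers, the scanner files of the 6 arrays were made with Agilent Feature Extraction 10.7.3.1, with probe positions on hg19. Their processed signal is an intensity, background-subtracted and detrended within each array and not normalized between arrays, per the file headers. The mean and background signals used for one alternative are likewise intensity values per the file headers, and the marks for spots well above background, saturated or outlying are of another kind, 0 or 1 (other unit), per the file headers. The table deposited by the authors holds log2 values that were normalized between arrays. The submitters' processing notes name limma without a version, and the method is not stated. Its columns have nearly equal quantiles and rank the spots of each array as the median spot signal does.

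Control spots and spots marked as outliers were left out, saturated spots would have been kept but none occurred, and spots of one probe were averaged. This left 50599 probes on 58717 spots. Probes were named from a RefSeq gene table of GRCh38.p14, used for names only. Of the probes, 30275 matched by transcript identifier, 3668 by symbol or older symbol, 15145 kept the name in the files and 1511 had none and were left out of the gene tests. Of 35566 named genes, 17333 were tested, namely those whose brightest probe (highest mean over the 6 arrays) was well above background on at least 3 arrays. The log2 processed signal minus the array's 75th percentile was analysed. A gene below background on every array of a group is given as a lower bound, with the dim side set at the lowest signal well above background. Such genes numbered 75 among those called. Of 1018 called genes with more than 1 measured probe, 217 had probes of opposite sign. The precision on each array was gauged from 902 probes printed at least 10 times, whose log2 signals had an SD of 0.063 to 0.096. The number of arrays limits the precision of all comparisons.

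The siRNA effect was fitted with limma 3.58.1 in R 4.3.3 (with the packages statmod 1.5.0 and data.table, version 1.17.8) with siRNA and cell line as terms, moderated by empirical Bayes (2 residual and 2.81 prior degrees of freedom). All tests were two-sided, adjusted by Benjamini and Hochberg over the genes tested, with a threshold of 0.05. The 3 contrasts between cell lines came from the same model. Changes within a line have no replicate. The 28 gene lists (922 names, of which 753 were tested) were written before the data were examined, as were the model, filter, threshold and the alternatives unless stated otherwise. They covered sphingolipid metabolism, the lysosome, autophagy, pigmentation, melanoma proliferative and invasive states, the neural crest, EMT, integrins, extracellular matrix, S phase, G2 and mitosis, p53 targets, apoptosis, stress responses, cholesterol, fatty acids, interferon, NF-kB, YAP and TGF-beta, glycolysis and hypoxia, oxidative phosphorylation, ribosomal proteins, reference genes and markers of fibroblasts, keratinocytes, endothelium and immune cells. Lists were compared with the other genes by limma's camera with a preset correlation of 0.01, and as alternatives with an estimated correlation and by fry, which tests a list alone. ASAH1 was left out of them. Each list's median per line was also set against 10000 random lists of similar signal.

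The genes named were set by a rule written beforehand. They are ASAH1, the 12 genes past the threshold with the largest rise and the 12 with the largest fall with one sign in all lines, up to 4 members per list past the threshold adjusted over the list alone or, failing that, of one sign, up to 5 state genes per contrast of lines, MITF, AXL, SOX10, NGFR, CCND1, ASAH2 and ACER1 to ACER3, and up to 4 list genes per line with the largest change in it. Further names (MCM10, ROCK1, ERBB3, CERS2, CERS6, TMEM158, PSAT1, SELENBP1, ARSK, SLIT1, ACTG2, KCNG1 and the genes of the symbol families) were chosen after their values were seen. XIST and Y-linked genes were passed over, and a few list members that the rule takes are not named.

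The model and list tests were tested on simulated data of 17333 genes. For siASAH1 minus siCtl with 200 changed genes, 88% of 4-fold and 2% of 2-fold changes were recovered and 6 unchanged genes were called. With 3000 changed genes, 78.6% were recovered and 3.72% of calls were false. In each simulation the noise of a gene had the same SD on all 6 arrays and was independent between genes. The unusual signal of the WM3912 and WM8 control arrays was not simulated, so these shares need not hold for the real calls. Alternatives were quantile normalization, the array median in place of the 75th percentile, normexp background correction with an offset of 50, the authors' table, no filter, a filter on all 6 arrays, the mean of all probes, every probe on its own, trended and robust variance, no cell line term, cell line as a random block and leaving out each line (replicate 1 is 501Mel, 2 is WM3912 and 3 is WM8). Chosen after the data were seen were a filter on the 4 arrays other than the WM3912 and WM8 control arrays, a fit without those 2 arrays and the cell line term, which leaves 1 control array (that of 501Mel) assumed to vary like the siASAH1 arrays and does not part line from siRNA, and a correction for the GC content of the probes. A change past the threshold under neither setting was counted as unchanged, and counts within 1.5 times as the same. The random block and the trended variance used the form of camera that takes the moderated statistics. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.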

Results

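RNA of 3 established human skin melanoma cell lines, labelled 501Mel, WM3912 and WM8, was measured on 6 single-colour Agilent expression arrays. Each line had 1 array after transfection with an siRNA against ASAH1 (siASAH1) and 1 after a control siRNA (siCtl), so each siRNA group held 3 arrays and each group within a line held 1. ASAH1 encodes acid ceramidase, the lysosomal enzyme that splits ceramide into sphingosine and a fatty acid. The 75th percentile of processed signal was 278 and 231 on the siCtl and siASAH1 arrays of 501Mel, 49.1 and 248 on those of WM3912, and 261 and 321 on those of WM8. In the same order, 50.8% and 49.4%, 36.2% and 49.3%, and 66.0% and 50.6% of spots were well above background. The WM3912 control array was therefore dimmer than the others, and the WM8 control array carried signal on more spots. The precision of every value is limited by the number of arrays.

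The first comparison asked how far the siRNA lowered its target. ASAH1 fell in each line, 51.3-fold in 501Mel, 35.5-fold in WM3912 and 26.9-fold in WM8. Its log2 signal relative to the array's 75th percentile was 6.49 ± 0.38 (SD, n = 3) with siCtl and 1.30 ± 0.32 (SD, n = 3) with siASAH1. The mean log2 change was -5.19 (SE 0.24, adjusted p = 0.0130 by limma), far larger than the spread between arrays of a group. The single ASAH1 probe, A_33_P3284463, lies on chromosome 8 from 17913967 to 17914026 (hg19) and was well above background on all 6 arrays. Its sequence was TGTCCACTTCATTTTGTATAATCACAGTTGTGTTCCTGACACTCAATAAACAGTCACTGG; whether it falls in a UTR or a coding exon was not given in the sources used here. Among other ceramidases, neutral ceramidase ASAH2 had a log2 change of -0.59 (adjusted p = 0.116, with the probe uncertain because of the near copy ASAH2B). The alkaline ceramidases ACER2 and ACER3 had log2 changes of -0.22 (adjusted p = 0.607) and -0.36 (adjusted p = 0.548), and ACER1 was too dim to be tested. ACER2 was above background on 2 of the 3 control arrays, and ACER3 on 1 of the 3 control and 2 of the 3 siASAH1 arrays. The call for ASAH1 ended without the background filter (adjusted p = 0.267) and when any 1 line was left out, with an adjusted p of 0.0560 without 501Mel, 0.0538 without WM3912 and 0.0656 without WM8, while the log2 change stayed between -5.42 and -4.95.

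**Figure D1:**
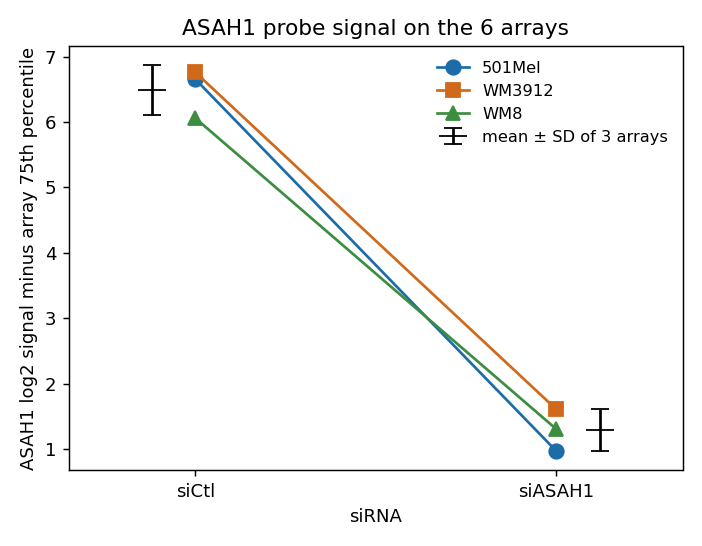
Signal of the ASAH1 probe on each of the 6 arrays (y axis, log2 signal minus the array's 75th percentile) by siRNA (x axis), with a line joining the arrays of one cell line and bars for the mean ± SD of 3 arrays. The control arrays averaged 6.49 and the siASAH1 arrays 1.30.

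The main comparison asked which transcripts changed when ASAH1 was lowered. Transcripts of 17 of 46 DNA replication genes and 17 of 45 mitosis genes fell, and those of 12 of 36 adhesion genes rose. These lists passed by camera with its preset correlation, but not with an estimated correlation. Transcripts of 8 of 16 neural crest genes rose, although that list did not pass. The melanocyte lineage factors MITF and SOX10 were not among the changed genes. Among single genes, VEGFC, the lymphatic vessel growth factor, rose by a log2 of 4.41 (SE 0.19), and PDE5A, which degrades cyclic GMP, by 3.65 (SE 0.17). TRPM1, a cation channel of melanocytes, fell by 4.62 on the log2 scale (SE 0.37). VEGFC was above background on 2 of the 3 control arrays and TRPM1 on 2 of the 3 siASAH1 arrays, so both sizes rest partly on background signal. Of 17333 genes tested, 2193 were higher and 1550 lower with siASAH1, and all 3743 had one sign in the 3 lines. With 2 residual degrees of freedom, passing the threshold all but requires one sign, so this is no separate evidence that the lines agree. Of these, 261 were at least 4-fold higher and 252 at least 4-fold lower, and 1890 of the higher and 1236 of the lower genes were protein coding.

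Among the other genes that rose furthest, IGDCC3, a cell surface protein of the immunoglobulin superfamily, rose by a log2 of 5.20 (SE 0.40). LINGO2, a leucine-rich repeat membrane protein, rose by 4.46, PDE7B, which degrades cyclic AMP, by 4.51, and the large scaffold protein AHNAK by 4.43, although its 3 probes ranged from 1.14 to 4.43. The collectin COLEC11 rose by 3.65. PRUNE2 rose by 3.53 and the channel protein PANX2 by 3.47 on their brightest probes, with other probes of these genes as low as 0.10 and 0.59. PDE7B and LINGO2 were above background on only 1 of the 3 control arrays and IGDCC3, AHNAK, COLEC11 and PANX2 on 2, so the sizes of their rises rest partly on background signal. Genes that were below background on every control array are given as lower bounds. AJAP1, a protein of adherens junctions, was at least 9.39-fold higher, the zinc finger protein TSHZ2 at least 4.77-fold and RPRM, which halts cells before mitosis, at least 3.46-fold.

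Among the genes that fell furthest, PMP2, a fatty acid binding protein of myelin, was at least 10.72-fold lower, the corticotropin-releasing factor family peptide UCN2 at least 15.1-fold and the olfactory receptor gene OR2C3 at least 11.96-fold, since all were below background on every siASAH1 array. The tight junction protein CLDN14 fell by 4.77 on the log2 scale (SE 0.31) and KLHL6, a Kelch family protein, by 4.24. PLS1, an actin bundling protein, fell by 4.05, MAP7D2, a microtubule-associated protein, by 3.74, and UBAP1L and DCPH1 by 4.36 and 3.85. PLS1, MAP7D2 and ANGPTL1 were above background on only 1 of the 3 siASAH1 arrays and CLDN14 and KLHL6 on 2, so the sizes of their falls rest partly on background signal. ANGPTL1, a secreted angiopoietin-like protein, fell by 3.94 on average (adjusted p = 0.0457), with -1.16 in WM3912 and -5.90 in WM8. The adjusted p of the other named genes that rose or fell furthest lay between 0.0130 and 0.0188. By limma 0 genes passed without the background filter (4972 at an unadjusted p under 0.05) or when any 1 line was left out (5936, 5098 and 4924 without 501Mel, WM3912 and WM8, with 1 residual degree of freedom). Without the WM3912 and WM8 control arrays 1364 genes were higher and 1076 lower, in a fit with no line term that sets the 1 control array left, that of 501Mel, against the siASAH1 arrays of 3 lines and takes its spread from those alone. Quantile normalization gave 836 and 781, and scaling by the array median gave 2019 and 149, so that the higher genes made up 93.1% of the calls in place of 58.6%.

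**Figure D2:**
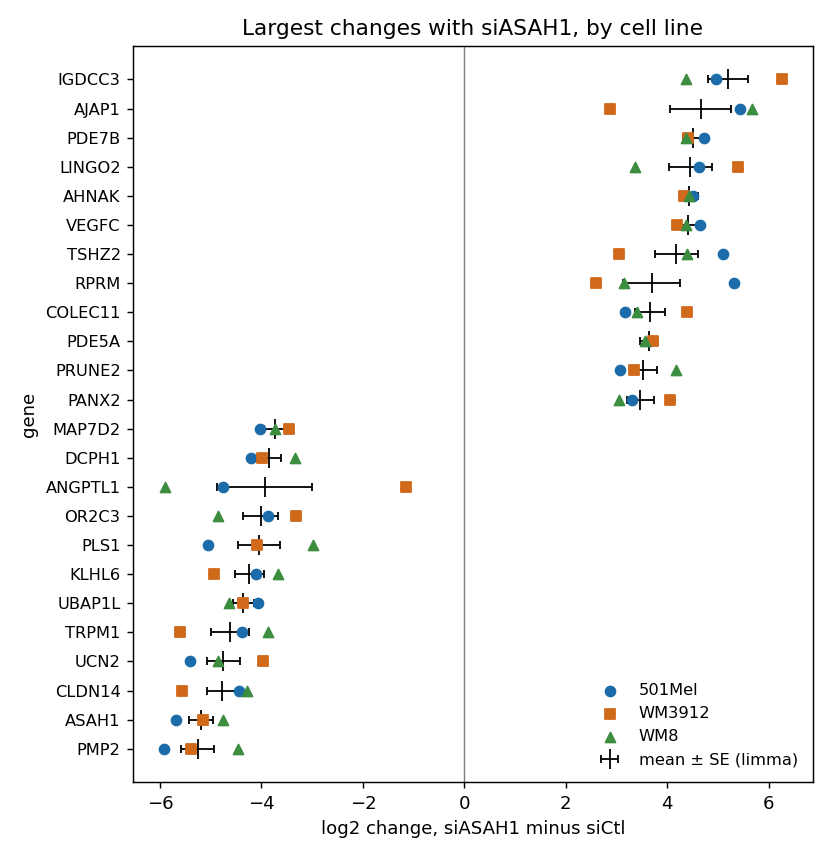
Log2 change (siASAH1 minus siCtl, x axis) of the 12 genes that rose and the 12 that fell furthest, with 1 symbol per cell line and the limma mean ± SE. AJAP1, TSHZ2 and RPRM were below background on every siCtl array, and PMP2, UCN2 and OR2C3 on every siASAH1 array, so their plotted changes are not measured folds; ANGPTL1 spans -5.90 to -1.16.

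Of 46 tested genes of S phase and DNA replication, 17 fell and 0 rose, and 26 fell when adjusted over the list alone. The thymidylate synthase TYMS fell by 2.07 on the log2 scale, the cyclin CCNE2 by 1.74, the transcription factor E2F8 by 1.54 and the replication factor MCM10 by 1.43, while the checkpoint adaptor CLSPN had a log2 change of -1.56 that passed only over the list alone. Of 45 tested genes of G2 and mitosis, 17 fell and 0 rose, with 22 lower and 1 higher when adjusted over the list alone. The mitotic kinase PBK fell by 1.74, ECT2, which drives cytokinesis, by 1.48, the anaphase activator CDC20 by 1.18 and the kinetochore protein NDC80 by 1.15. The lists' median log2 changes were -0.69 and -0.67, and both lay below the other genes by camera (adjusted p = 1.1e-08 and 2.4e-08), but not with an estimated correlation between genes (adjusted p = 0.911 with an estimated correlation for each). The medians were negative in each line, at -0.63, -0.78 and -0.51 for S phase and at -0.69, -0.57 and -0.50 for mitosis in 501Mel, WM3912 and WM8. Each lay below those of all 10000 random lists of similar signal. Random lists do not keep the correlation between genes, and a line has 1 pair of arrays, so this rank does not measure replication. With 501Mel as the 1 control array left, the medians of S phase and mitosis were -0.93 and -0.87. Scaled by the array median, which set the median of all genes at 0.78, they were 0.04 and 0.07, still below the other genes. The cyclin CCND1, which acts earlier in the cycle, had a log2 change of 0.22 (adjusted p = 0.447).

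Of 28 targets of p53 and genes of cell cycle arrest, 4 rose and 8 fell (5 and 11 adjusted over the list alone, camera adjusted p = 0.157). TIGAR, which limits glycolysis and was above background on 2 of the 3 siASAH1 arrays, fell by 3.31 and the death receptor TNFRSF10B by 2.60, while the cyclin-dependent kinase inhibitor CDKN1C rose by 2.06 and TP53I3 by 1.89. Of 33 regulators of apoptosis, 6 rose and 5 fell (9 and 8 adjusted over the list alone, camera adjusted p = 0.718). The pro-apoptotic protein BIK rose by 2.36, while PMAIP1, which encodes NOXA, fell by 1.88.

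Of 36 tested integrin and focal adhesion genes, 12 rose and 2 fell, and 13 rose and 2 fell when adjusted over the list alone. The focal adhesion protein LPP rose 5.67-fold, the laminin-binding integrin chain ITGB4 by a log2 of 2.35, the small GTPase RHOB by 1.81 and the caveolae protein CAV1 by 1.81, while the kinase ROCK1 fell by 1.78. ITGB4 was above background on only 1 of the 3 control arrays and LPP on 2. The list's median log2 change was 0.39 (camera adjusted p = 0.00685, and adjusted p = 0.911 with an estimated correlation), and the list did not pass in the fit with 1 control array left (adjusted p = 0.0631). Of 28 genes of extracellular matrix and its remodelling, 9 rose and 1 fell (9 and 4 adjusted over the list alone, camera adjusted p = 0.193). The collagen chain COL6A1 rose by 1.67 and the matrix protease MMP15 by 1.62, while ECM1 fell by 1.72. The laminin chain LAMB1 rose by 2.44 on its brightest probe, with another of its probes at -1.05.

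Of 21 genes of the invasive state, 7 rose and 0 fell, with 11 and 1 adjusted over the list alone (median log2 change 0.71, camera adjusted p = 0.0661). The list passed with quantile normalization (adjusted p = 0.0340), the array median (0.0110), normexp correction (0.0340), the authors' table (0.0262), a filter on all 6 arrays (0.0493) and without WM8 (0.0323). Among its genes, the matricellular protein CCN1 rose by 2.57 and the activin antagonist FST by 1.58, and the kinase gene CDK14 was at least 1.30-fold higher. MYOF, a membrane repair protein, was not past the threshold (adjusted p = 0.0641) and below background on every control array. Of 16 neural crest and dedifferentiation genes, 8 rose and 1 fell, with 8 and 2 adjusted over the list alone (median log2 change 1.05, camera adjusted p = 0.134, and 0.0110 with the array median). The glutamate transporter SLC1A3, above background on 2 of the 3 control arrays, rose by 2.44, the transcription factor POU3F2 (BRN2) by 2.35, the ERBB receptor ligand NRG1, above background on 1 of the 3 control arrays, by 2.30 and ID3 by 1.85, while the receptor ERBB3 fell by 0.82 on its brightest probe, with another of its probes at 0.86. Of 49 genes of the proliferative state, 8 rose and 11 fell, with 10 and 13 adjusted over the list alone (camera adjusted p = 0.135). That list lay below the other genes with quantile normalization (adjusted p = 0.00608), normexp correction (0.00571) and the authors' table (0.01001). CAPN3 fell by 1.76 beside TRPM1, and the semaphorin SEMA6A, above background on 2 of the 3 control arrays, rose by 1.82. Of 34 pigmentation genes, 5 rose and 6 fell, as many as when adjusted over the list alone (camera adjusted p = 0.316). The receptor MET fell by 2.36 and the mitochondrial coactivator PPARGC1A by 1.82, while OCA2, a melanosome membrane transporter, rose by 1.97. MITF, the master regulator of melanocytes, had a log2 change of -0.39 (adjusted p = 0.238), with -0.61, -0.55 and -0.01 in 501Mel, WM3912 and WM8. The log2 change was 0.00 for SOX10 (adjusted p = 0.997) and -0.69 for the receptor kinase AXL (adjusted p = 0.275), and NGFR was too dim to be tested.

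Of 11 tested regulators of the epithelial-mesenchymal transition and cadherins, 4 rose and 1 fell (the same counts adjusted over the list alone, camera adjusted p = 0.527). TCF3 rose by 2.05, TWIST1 by 1.59, SNAI2 by 1.47 and the intermediate filament protein VIM by 0.96. The 2 measured TWIST1 probes rose by 0.67 and 1.59, and the mean over all 5 of its probes, dim ones included, was -0.086. The list's median was -0.01 and its mean 0.35, so that the median differed in sign from the mean and the test. Of 21 targets of YAP and TGF-beta, 10 rose and 3 fell (11 and 5 adjusted over the list alone, camera adjusted p = 0.193, and 0.0337 with a filter on all 6 arrays). FOXF2 rose by 3.31, whereas F3, the tissue factor that starts clotting, fell by 2.59 and the growth factor TGFB2 by 2.43. FOXF2 was above background on 1 of the 3 control arrays, and F3 and TGFB2 on 1 of the 3 siASAH1 arrays. F3 and TGFB2 were below background on both WM3912 arrays, so the sizes of their falls rest partly on background signal.

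In the target's own pathway, 7 of 42 sphingolipid genes rose and 2 fell, the same counts as when adjusted over the list alone (camera adjusted p = 0.451). SGPL1, which degrades sphingosine-1-phosphate, rose by 1.56, and the ceramide synthases CERS2 and CERS6 rose by 1.28 and 0.84, with another CERS6 probe at 0.03. In ganglioside synthesis B4GALNT1 rose by 2.04 while ST3GAL5, which makes GM3, fell by 1.96. Of 50 lysosome genes, 5 rose and 0 fell, of which 1 passed adjusted over the list alone (camera adjusted p = 0.0661, with 0.0306 for the mean of probes and 0.0391 for trended and robust variance). Among all 17333 genes tested, 2193 rose and 1550 fell, a higher share of rises than among the lysosome genes. The hexosaminidase chain HEXA rose by 1.43. Of 38 autophagy genes, 9 rose and 1 fell, with 13 and 2 adjusted over the list alone (camera adjusted p = 0.125). ATG14, above background on 1 of the 3 control arrays, rose by 2.19, the initiating kinase ULK1 by 2.07 and its partner ATG13 by 1.34, while the protease ATG4C fell by 1.95. B4GALNT1 was above background on 2 of the 3 control arrays.

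Of 27 genes of cholesterol synthesis, 6 rose and 4 fell (6 and 5 adjusted over the list alone, camera adjusted p = 0.874). INSIG1, which restrains sterol synthesis, fell by 1.25. LSS fell by 1.08 on its brightest probe, with another of its probes at 1.44. Of 34 genes of fatty acid and glycerolipid metabolism, 3 rose and 3 fell, as many as when adjusted over the list alone (camera adjusted p = 0.964). The acyl-CoA synthetases moved apart, with ACSL4, above background on 2 of the 3 control arrays, up by 1.82 and a log2 change of -1.57 for ACSL1, while ACACB, an acetyl-CoA carboxylase, fell by 1.75 and FABP7 rose by 1.17.

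Of 43 genes of oxidative phosphorylation, 3 rose and 2 fell, with 1 and 1 adjusted over the list alone (camera adjusted p = 0.323). Cytochrome c, CYCS, fell by 1.88. Of 30 genes of glycolysis and hypoxia, 6 rose and 6 fell, with 8 and 8 adjusted over the list alone (camera adjusted p = 0.718). ANKRD37 rose by 2.25 and NDRG1 by 1.88, whereas the collagen hydroxylase P4HA1 fell by 1.87 and the hexokinase HK1 was 3.99-fold lower. That list's median of 0.03 and mean of 0.01 were positive although the test placed it below the other genes. Of 35 genes of the unfolded protein and integrated stress responses, 4 rose and 2 fell, as many as when adjusted over the list alone (camera adjusted p = 0.878). The pseudokinase TRIB3 rose by 1.81, DDIT4, which restrains mTORC1, by 1.53, and the transcription factor ATF3 by 1.32 on its brightest probe, while the folate enzyme MTHFD2 fell by 1.84. Another ATF3 probe was at -0.41.

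Of 32 interferon response genes, 3 rose and 6 fell, with 5 and 9 adjusted over the list alone (camera adjusted p = 0.177). The RNA sensor IFIH1 rose by 1.45, while ISG15 fell by 1.32, IFIT1 by 1.16 and IFIT2 by 1.17, although IFIT2, above background on 2 arrays of each group, was at 0.21 after quantile normalization and 0.056 in the authors' table. Of 19 genes of NF-kB and secreted inflammatory factors, 4 rose and 2 fell, with 5 and 4 adjusted over the list alone (camera adjusted p = 0.718). The chemokine CCL2 rose by 2.26 and CXCL2 fell by 3.08, with CCL2 above background on 2 of the 3 control arrays and CXCL2 on 2 of the 3 siASAH1 arrays. Of 45 cytosolic ribosomal protein genes, 3 rose, namely RPL4 by 0.76, RPL30 by 0.72 and RPL22 by 0.71, and 0 fell. The brightest RPL22 probe is placed on chromosome 14 (hg19), away from the gene itself, so its value is uncertain, and RPL7 was at 0.70 (adjusted p = 0.0530). None of them passed adjusted over the list alone, and the list lay above the other genes by camera (adjusted p = 0.0276, and adjusted p = 0.911 with an estimated correlation). Its median was 0.48 in 501Mel, -0.02 in WM3912 and 0.46 in WM8, and the list did not pass without 501Mel (adjusted p = 0.235) or without WM8 (adjusted p = 0.111), nor with quantile normalization (0.141), the array median (0.224) or normexp correction (0.0508). Of 20 reference genes, 4 rose (4 adjusted over the list alone, camera adjusted p = 0.718), namely TFRC by 1.09, EEF2 by 1.03, YWHAZ by 0.95 and B2M by 0.75, with another YWHAZ probe at 0.03.

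Of markers of other cell types, none of 5 fibroblast markers or 2 endothelial markers passed (camera adjusted p = 0.508 and 0.912). The desmosome protein DSP, 1 of 6 keratinocyte and epithelial markers, fell by 1.83 (camera adjusted p = 0.451). Of 9 immune cell markers, 0 rose and 2 fell (camera adjusted p = 0.0661), namely CD68 by 1.88 and LCP1 by 1.49. The immune list passed with the array median (adjusted p = 0.0143), a filter on all 6 arrays (0.0376), the mean of probes (0.0485) and without 501Mel (0.0233). Without 501Mel, only the pairs with the dim WM3912 control array and the WM8 control array with signal on more spots remain. CD68 and LCP1 fell in all 3 lines, whereas PTPRC changed by 0.07, -0.16 and -5.10 in 501Mel, WM3912 and WM8. CD3D changed by -0.37, -2.88 and -0.31. Counts for these 4 lists were the same adjusted over the list alone. Of all 28 lists, 4 passed by camera with its preset correlation, 0 with an estimated correlation, 0 by fry and 14 without the background filter. In the fit without the WM3912 and WM8 control arrays, where 1 control array of 501Mel faces 3 lines with no line term, 8 lists passed, which included those of the invasive state (adjusted p = 0.0118), the proliferative state, extracellular matrix, p53 targets and interferon response and left out the integrin list.

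**Figure D3:**
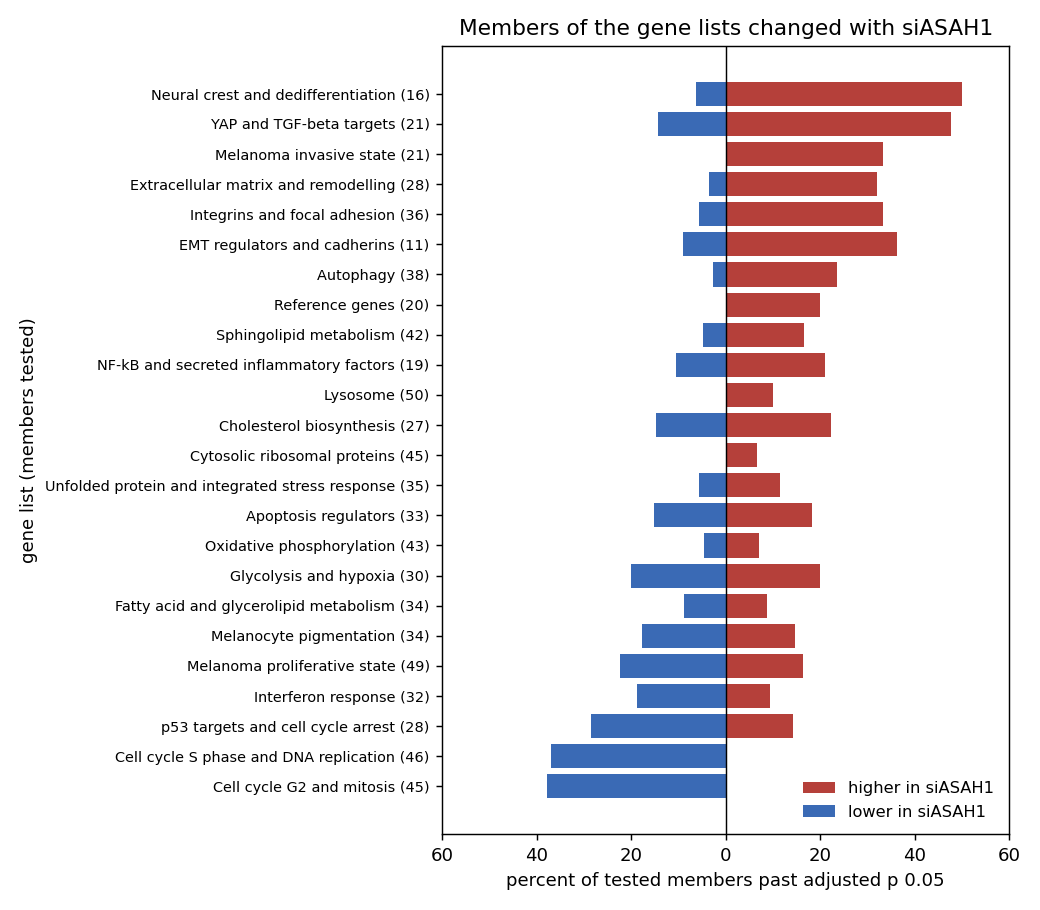
Percent of the tested members of each gene list that were past an adjusted p of 0.05 (x axis), higher to the right and lower to the left, with the number tested in brackets. Among all 17333 genes tested, 2193 were higher and 1550 lower. The S phase and mitosis lists had 37.0% and 37.8% of members lower and 0 higher, although their medians turned to 0.04 and 0.07 under scaling by the array median, below the median of 0.78 of all genes.

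A further comparison asked how far the lines responded alike. PDE5A was higher by 3.66, 3.71 and 3.57 on the log2 scale in 501Mel, WM3912 and WM8, and SGPL1 by 1.56, 1.62 and 1.49. In all 3 lines 904 genes were at least 2-fold higher and 747 at least 2-fold lower with siASAH1, together 1651, where independent lines would share 33.5 and 36.4. The log2 changes of 501Mel and WM3912 correlated across 17333 genes with Pearson's r of 0.612 (Spearman's rho 0.595), those of 501Mel and WM8 with 0.567 (0.612) and those of WM3912 and WM8 with 0.625 (0.682). These 3 correlations are across genes, which are not independent replicates. The largest changes of list genes in a single line included FOXF2 in 501Mel (at least 13.1-fold higher) and, in WM8, log2 changes of the basement membrane collagen COL4A1 (-5.28) and the leukocyte phosphatase PTPRC (-5.10), both set against the control array with signal on more spots. The mean changes of COL4A1 and PTPRC over the lines did not pass (adjusted p = 0.148 and 0.303). The fibrillar collagen COL1A1 was at least 2.25-fold higher with siASAH1 in 501Mel, where its control array was below background, below background on both arrays of WM3912 and 21.3-fold lower in WM8, against that same WM8 control array (mean change, adjusted p = 0.819). With 1 pair of arrays per line, the difference was not tested. The count of shared genes was 813 after normexp background correction and 1073 in the authors' table, and 2776 genes were changed alike in the pair of lines other than 501Mel.

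The last comparison set the cell lines against each other, with 2 arrays each. No melanoma state, pigmentation or neural crest gene differed between lines past the threshold. The log2 signal of MITF, for example, spanned 0.60 over the 3 control arrays and 0.01 over the 3 siASAH1 arrays, and the median span of 104 such genes was 0.60 and 0.36. SLC1A3 spanned 3.93 over the siASAH1 arrays, and the largest span there, 4.13, was that of TMEM158, chosen after its values were seen and below background on an array. By limma, 0 genes differed between 501Mel and WM3912, 0 between 501Mel and WM8 and 0 between WM3912 and WM8, with smallest adjusted p of 0.0639, 0.753 and 0.128. At an unadjusted p under 0.05 there were 1209, 709 and 1590 genes, where chance gives 867. In data simulated for 501Mel minus WM8 on 17333 genes, 99% of 16-fold differences and 80% of 4-fold differences were recovered when 200 genes differed. In that simulation 15 unchanged genes were called. Some genes chosen after their values were seen did differ on both pairs of arrays without passing. The counts of 0 therefore do not show that large differences between lines were absent. PSAT1, an enzyme of serine synthesis, was at least 23.0-fold higher in 501Mel than in WM3912 on the control arrays and 35.7-fold on the siASAH1 arrays, and at least 11.6-fold and 28.8-fold higher in WM8 than in WM3912. SELENBP1, a selenium-binding protein, was at least 15.6-fold and 12.1-fold higher in 501Mel than in WM3912. The sulfatase gene ARSK was 5.98-fold and 4.06-fold lower in 501Mel than in WM8. Across genes, arrays of different lines with siASAH1 correlated with r of 0.983 to 0.989. Arrays with different siRNAs correlated with 0.935 to 0.959 within a line and with 0.927 to 0.954 between lines. Scaling by the array median called 52, 16 and 37 genes, and a trended and robust variance 121, 6 and 195.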

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

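The tests of the line differences, of the WM3912 and WM8 control arrays and of other cell types were chosen only after the results were seen, and the correction for GC content was added after the data were seen; the splits of the arrays and the test by kind of gene were planned.

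Little separation by line was seen between the arrays labelled as 3 melanoma lines. By limma 0 genes differed between lines, and siASAH1 arrays of different lines correlated across genes at 0.983 or more, above the highest value within a line (0.959). That comparison sets arrays of one siRNA against arrays of different siRNAs, so the siRNA effect alone can give it. Between arrays of different siRNAs, r was 0.935 to 0.959 within a line and 0.927 to 0.954 between lines. Whether noise on the control arrays of WM3912 and WM8 adds to the pattern stays open, since the value of 0.983 is part of the pattern itself and r within a line also holds the siRNA effect. The difference between 501Mel and WM8 on control arrays hardly recurred on siASAH1 arrays (r = 0.0894 across genes), as RNA of one source under both labels would give. A shared source is a candidate explanation for that pair. The unusual signal of the WM8 control array could also lower this r, so r alone cannot settle it. On both pairs of arrays 173 genes differed 2-fold the same way, against 86 in opposite ways. Among genes chosen after their values were seen, ARSK, SLIT1 (12.7-fold and at least 3.86-fold), ACTG2 (at least 5.58-fold and 5.64-fold) and KCNG1 (at least 6.17-fold and 5.54-fold) differed on both. Deviations from the group mean correlated at 0.097 within 501Mel and 0.213 within WM8, against 0.092 and -0.011 between them. For WM3912 and WM8 the r of 0.309 lay between the bounds set. Between these lines 446 genes, PSAT1 and SELENBP1 among them, differed 2-fold the same way on both pairs of arrays, against 115 in opposite ways. Deviations from the group mean correlated at 0.319 within WM3912 and 0.213 within WM8, against -0.301 and -0.174 between these lines. These counts rest on the same arrays as that r, and subtracting a mean of 3 arrays by itself lowers r between lines. The line difference recurred in part, which does not settle whether that pair shares a source. Similar expression in the lines in these cultures stays open as untested.

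The number of genes changed with siASAH1, 3743, came from 3 lines of which 2 had an unusual control array. Signal of those 2 arrays as the whole cause is argued against by 501Mel, where 91.0% of the 2776 genes changed at least 2-fold alike in WM3912 and WM8 took the same sign (99.0% of the higher and 82.0% of the lower genes). GC content of the probes is argued against as well, with 4004 genes past the threshold after the correction. Splitting the 6 arrays 3 against 3 gives 10 splits, too few for a share under 0.05; without the line term the real split called 4241 genes and the highest other 0, in 1 of 10 splits. Effects of the siRNA other than through ASAH1 and of ASAH1 itself stay open, as no second siRNA was given in the sources used here.

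For the list calls the splits say less. All 10 of the 10 splits called as many lists as the real one (3 without the line term, 4 with it), and the highest other called 8, or 7 with the line term. Every other split still parts the siRNAs in part, with 2 arrays of one siRNA and 1 of the other on each side, so these calls are not free of the siRNA. The size of the list medians ranked differently. For S phase the real split gave 0.69 against 0.46 for the highest other and for mitosis 0.67 against 0.47, while for integrins it gave 0.39 against 0.40 and for ribosomal proteins 0.30 against 0.43.

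On the WM8 control array 6099 genes were well above background that were so on no other array, against at most 339 on any other, in data the comparisons do not use. RNA of another cell type as the cause is argued against, since 49.9% of 361 olfactory receptor genes, which few tissues express, were among the genes well above background there, against 4.71% to 10.8% elsewhere. Signal independent of the kind of gene is a candidate explanation, since among genes dim on the other arrays the share above background was 45.3% for olfactory receptor genes and 40.7% for other protein-coding genes, a ratio of 1.11. What produced such signal stays open, and no biological explanation was tested.

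On the WM3912 control array the spike-in probes, also unused in the comparisons, stood 2.87-fold above the mean of the other 5 arrays, beside a 75th percentile 5.42-fold below theirs. COL1A1 had log2 changes of opposite sign in 501Mel (3.15) and WM8 (-4.41), a difference that was not tested, with 1 pair of arrays per line. The 501Mel control array was below background, which leaves at least 2.25-fold, and the WM8 value rests on the WM8 control array with its unusual signal.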

How the results depend on the processing

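The GC correction, the filter on 4 arrays and the fit without the WM3912 and WM8 control arrays were chosen only after the results were seen. ASAH1 stayed negative in every alternative and past the threshold except without the filter (-5.19, adjusted p = 0.267) and without any 1 line (-5.42 to -4.95, adjusted p 0.0538 to 0.0656). Counts of higher and lower genes moved to 836 and 781 with quantile normalization (1549 shared with the 3743), 2019 and 149 with the array median, which shifts the median of all genes to 0.78, 1350 and 1195 with the mean of probes, 3835 and 2399 with trended and robust variance, 1364 and 1076 without the 2 control arrays (1945 shared, with 1 control array left that is assumed to vary like the siASAH1 arrays, and no line term), and 0 and 0 without the filter, where 35566 genes were tested, or without any 1 line, which leaves 1 residual degree of freedom. They stayed within 1.5 times under the GC correction and the filter on 4 arrays.

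Genes changed 2-fold in all lines were 813 with normexp correction, 1073 in the authors' table and 2040 to 2776 without 1 line, which asks only for the lines left. The mean r of changes between lines was 0.559 with quantile normalization, 0.725 with normexp, 0.691 in the authors' table, 0.286 without the filter and 0.765 with a filter on all 6 arrays. For 501Mel against WM3912, 501Mel against WM8 and WM3912 against WM8, genes past the threshold were 52, 16 and 37 with the array median, 10, 2 and 12 with normexp, 7, 0 and 4 in the authors' table, 13, 0 and 13 with the filter on all 6 arrays and 121, 6 and 195 with trended and robust variance. Lists past the threshold were 14 without the filter, 7 with the filter on all 6 arrays, 8 without the 2 control arrays and 0 with an estimated correlation or fry. Both cell cycle lists passed under every alternative that tested lists and kept camera's preset correlation, with 4 lists when any 1 line was left out. Lists were not tested with every probe on its own.

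Reversed were IFIT2 (0.21) with quantile normalization and IFIT2 (0.056) in the authors' table. TWIST1 (-0.086) and LSS (0.18) reversed with the mean of probes, and COL1A1 (3.18) without the 2 control arrays. The mean of probes takes in dim probes, and for TWIST1 only 2 of 5 probes were measured, each of them higher with siASAH1. Of 115 named genes, 102 lost the threshold without the filter or any 1 line, 32 with the array median, 22 without the 2 control arrays, 22 with quantile normalization and 13 with the mean of probes. Except where a reason is given, the cause was not tested. Signal over background limits 75 called genes to lower bounds.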

Other observations

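The families of genes below, their tests and the genes named were chosen only after the results were seen. Histone genes had a lower median change than any list fixed beforehand. Of 72 tested, 44 fell and 2 rose with siASAH1, with a median log2 change of -1.31, at -0.65 in 501Mel, -1.84 in WM3912 and -1.49 in WM8. Examples are the linker histone H1-5, which fell by 1.84, the core histone gene H2BC7, which fell by 2.06, and the variant H2AX, which marks DNA breaks and fell by 1.63, while H1-10 rose by 0.94. Core histones are made mostly in S phase, and 17 of 46 genes of the S phase list fell, but a link between these falls was not tested. How fully the amplification and labelling method copies histone transcripts was not tested either. The histone median fell least in 501Mel, and the control arrays of WM3912 and WM8 were the unusual ones. That histone genes lie lower as a group may be read from camera over 212 families of symbols (adjusted p = 4.2e-13), although not with an estimated correlation (adjusted p = 0.991 with an estimated correlation). The median lay below that of all genes under each scaling, by -1.61 after quantile normalization and -1.35 with the array median, and the highest median of other splits was 0.89 in size. Near-identical histone copies share probe sequence, so single members are uncertain.

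Of 8 tested homeobox genes of the HOXB cluster, which set position along the body axis, 5 rose and 0 fell, with a median log2 change of 1.92 (camera adjusted p = 0.0338, and adjusted p = 0.991 with an estimated correlation). The median was 1.17 in 501Mel, 2.21 in WM3912, set against its dim control array, and 1.26 in WM8, and it was 1.44 in the authors' table. With normexp correction the median was 0.92 above that of all genes. HOXB5 and HOXB7 were above background on 2 of the 3 control arrays, and HOXB6 rose by 2.28, HOXB5 by 2.27, HOXB9 by 2.19 and HOXB7 by 2.05. Of 386 zinc finger genes named ZNF, 96 rose and 17 fell (median 0.46, camera adjusted p = 0.00240, and adjusted p = 0.991 with an estimated correlation). Of 50 genes whose symbols start with EIF, which are mostly translation initiation factors beside kinases and binding proteins of such factors, 11 rose and 2 fell (median 0.46, camera adjusted p = 0.0338, and adjusted p = 0.991 with an estimated correlation), with the helicase EIF4A2 up by 2.04 and EIF1B by 1.19, while EIF4A3 fell by 1.05. Of 50 genes named RPL, 4 rose and 0 fell (median 0.33, camera adjusted p = 0.0330, and adjusted p = 0.991 with an estimated correlation). Their median was 0.10 in WM3912 and only 0.07 above that of all genes after quantile normalization. RPL4, RPL30 and RPL22 belong both to this family and to the ribosomal protein list described earlier, so the family is no independent observation. The medians of these 4 families lay above that of all genes under each scaling.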
